A study of Mus musculus with 2 samples.

How the data were processed

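RNA was measured by poly(A)-selected paired-end sequencing in 2 libraries of Ter119-positive erythroblasts from mouse fetal liver at embryonic day 14.5, per the labels. The deposited tables give values per gene and per transcript for each library separately. Alignment was to mm10 with the GENCODE M4 annotation, per the listing deposited beside the tables; the aligner, the quantifier, their versions and any strand setting are not given in the sources used here. The column names, per the file headers, are those that the program RSEM writes. The deposited expected counts are estimates in which the authors' quantifier divided reads that match several genes, so they need not be whole numbers. The deposited TPM values are corrected for transcript length and have the same sum in each library. The authors also deposited FPKM values and posterior mean TPM values, used as alternatives. The deposited percent of each gene's TPM that falls to each transcript was used for the transcript shares.

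Each gene table held 69691 rows, of which 43346 were Ensembl genes, 96 spike-in sequences, 1 PhiX sequence and 26248 numeric identifiers; the rows without an Ensembl identifier held 0 counts in both libraries. A symbol was found for 42462 of the Ensembl genes, and 884 had none. Symbols, positions and GC content came from the GENCODE M21 annotation of the same mm10 assembly and a table of gene names, with GC content as the mean over a gene's transcripts. Total expected counts were 51190555 and 44256287, and 14475 and 14610 genes had a count. The 10 most abundant genes took 75.9% and 75.1% of the counts. The mean fragment length implied by the effective lengths was 143 and 137 bases. A count of 0 was taken as at most 3 counts, 0.0586 and 0.0678 CPM.

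Expected counts were rounded to whole numbers for the count tests. Library sizes were scaled by the trimmed mean of M values in edgeR 4.0.16 (R 4.3.3), with factors 0.996 and 1.00. With 1 group there was no test between conditions. The biological coefficient of variation came from the common dispersion of edgeR with an intercept alone, over the 9043 genes its expression filter kept. Genes that differed between the libraries were found with a two-sided exact conditional binomial test on genes with 10 or more counts in both libraries together, with Benjamini-Hochberg adjustment over 10955 genes and a threshold of 0.05; at an unadjusted threshold of 0.05, 5474 genes passed. Correlations were computed on log2(TPM + 1).

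The composition of 30 gene lists, the tests and the alternatives were fixed before the data were examined. For levels, the median of the mean log2(TPM + 1) of a list was placed among 10000 random lists of the same size drawn from protein-coding genes. For differences between the libraries, the median log2 ratio of scaled CPM, with a pseudocount of 1 and over genes with a mean CPM of 1 or more, was placed among 10000 random lists matched in 20 bins of expression. A list was called outside when it lay under percentile 2.5 or over 97.5. The percentiles describe these libraries, and genes are not replicates. Of the red cell redox list 1 member was not analysed here. Transcript shares were given for genes with 50 or more counts in both libraries.

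The genes named were chosen by a fixed rule. For levels it took all globin genes, the 20 protein-coding genes with the highest mean TPM, the 3 highest and the 1 lowest of each list, and Gata1, Klf1, Tal1, Epor, Kit, Gata2, Spi1, Tfrc, Alas2, Slc4a1, Alb, Ptprc and Xist. For the comparison of the libraries it took the 10 protein-coding genes with the largest ratio in each direction among those past the threshold with 100 or more counts in at least 1 library. Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen. Sharing of sequence between genes was measured as the percent of the 31-base words of a gene that also occur, on either strand, in M21 transcripts of another gene. An expected count was called whole when it lay within 0.01 of a whole number in both libraries.

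The alternatives were DESeq2 1.42.0 size factors or total counts in place of the edgeR factors, other count and TPM minima, other pseudocounts, FPKM, posterior mean TPM or counts in place of TPM, other denominators and backgrounds, and each library alone. A GC correction of the ratios by the medians of 20 GC bins, GC-matched random lists, and the globin share of Hba-a1, Hbb-bs and Hbb-bt alone were added after the data were seen. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures.

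The procedures were tested on simulated data. For the binomial test, counts were drawn for the real genes with counting error alone and 200 genes changed, and 11059 genes were tested. The rates that follow therefore do not cover further spread between real libraries. Of the changed genes, 52.9% were recovered at 1.5-fold, 58.7% at 2-fold and 72.5% at 4-fold, and among those with 100 or more counts 81.8%, 94.1% and 100%. All 123 recovered genes had the right direction, and 4 unchanged genes were called. A simulated coefficient of variation of 0.2 was estimated as 0.198. Of simulated lists of 20 genes that had not been moved, 5% were called for shifts and 7% for levels, and of lists that had been moved, by 0.5 log2 units for shifts and 4 for levels, 100% and 98%.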

Results

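Poly(A)-selected RNA from mouse fetal liver erythroblasts, the nucleated precursors of red cells, was sequenced as paired ends. The cells carried Ter119, a surface antigen of the red cell lineage, and came from pooled male and female embryos at day 14.5 of gestation. The series holds 1 group of 2 libraries, which the labels call biological replicates 1 and 2, named library 1 and library 2 from here on. The labels give both libraries the same donor entry but separate biosamples, so the spread between them may be partly technical. Library 1 held 51190555 expected counts and library 2 held 44256287, of which 14155918 and 12299432 lay outside the globin genes. With 1 group there was no condition to compare, and the data were examined for the makeup of the erythroblast transcriptome and for the agreement of the replicates. Values are mean TPM, the length-corrected relative abundance of transcripts, ± SD over the 2 libraries (n = 2) unless single libraries are named. Intervals on counts cover counting error only, and values of genes that share reads with near-identical copies or overlap other genes are uncertain.

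Adult globin messenger RNAs filled most of the transcriptome. The 8 globin genes together took 85.2% ± 1.13 of all TPM, and 72.3% ± 0.0976 of the expected counts. Hba-a1, an adult alpha globin gene (chromosome 11, 32283511 to 32284465 in mm10), had the highest level of any gene at 471122 ± 10054 TPM. Hbb-bs, the major adult beta globin gene of this annotation (chromosome 7, 103826534 to 103828096), followed at 332512 ± 22313 TPM and Hbb-bt (chromosome 7, 103812524 to 103813996) at 46227 ± 22208 TPM. The alpha-like genes summed to 1.25 ± 0.0324 times the beta-like genes in TPM, with 1.27 in library 1 and 1.23 in library 2. By expected counts, which are not corrected for transcript length, the ratio was 1.45 ± 0.211, with 1.30 in library 1 and 1.6 in library 2, so the direction of the difference between the libraries depends on the unit.

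Embryonic globins were a small part of the total. Hbb-y and Hbb-bh1, the embryonic beta-like genes, made up 0.0889% ± 0.0935 of beta-like TPM, 0.0228% in library 1 and 0.155% in library 2. Hbb-y (chromosome 7, 103851749 to 103853216) stood at 81.8 TPM in library 1 and 584 TPM in library 2. Hba-x, the embryonic alpha-like gene, had 181 ± 13.1 TPM and Hbb-bh1 had 4.44 ± 0.0566 TPM. Hbb-bh2, a minor gene of the same cluster, had 4 counts in library 1 and 0 in library 2, where a count of 0 allows up to 3 counts or 0.0678 CPM. The median of the embryonic globins lay at percentile 99.99 of random lists of protein-coding genes, and the alpha-like, beta-like, adult alpha and adult beta lists each lay at percentile 100.

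The split between near-identical adult copies differed between the libraries. Hbb-bt took 16.4% of adult beta TPM in library 1 and 8.06% in library 2, whereas the sum of Hbb-bs and Hbb-bt was 378665 and 378813 TPM but 314716 and 277520 CPM. Hba-a2 (chromosome 11, 32296489 to 32297298), a copy of Hba-a1, was assigned 2961 and 637 TPM. The adult alpha sum was 472921 ± 11698 TPM, and 408501 and 443882 CPM. The expected counts of these 4 genes were not whole numbers, since shared reads had been divided among them, so the level of each single copy is uncertain.

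**Figure D1:**
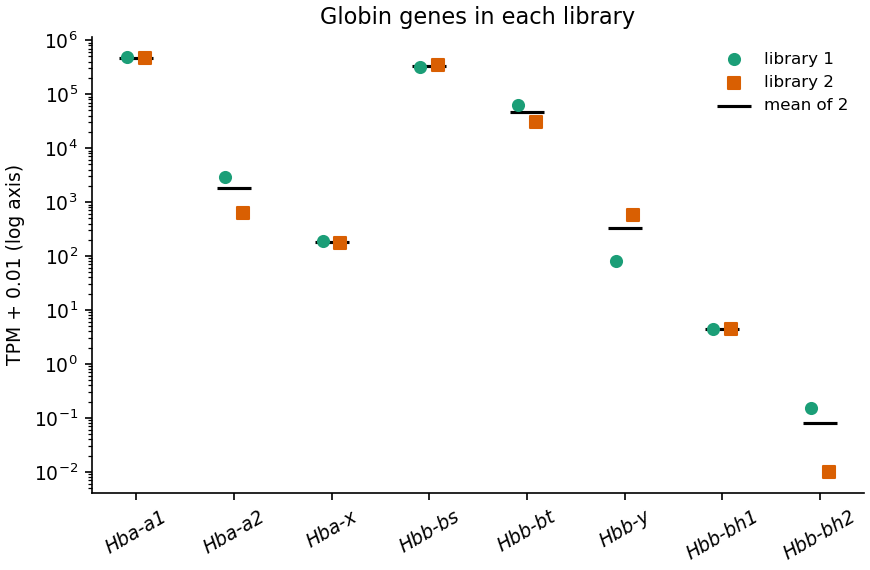
Each point is the TPM of a globin gene in 1 library, on a log axis of TPM + 0.01, for library 1 and library 2. The 2 libraries nearly coincide for Hba-a1 and Hbb-bs, while Hbb-y stands at 81.8 and 584 TPM.

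Outside the globins, histones, ferritins and ribosomal proteins led among protein-coding genes. The 20 most abundant protein-coding genes took 89.5% of TPM and the first 100 took 93.0%. Of the TPM outside the globins, the 20 most abundant genes that are not globins held 32.1%, with the non-coding Gm42418 (2140 ± 1508 TPM) among them. Hist1h2ap (9644 ± 659 TPM) and Hist1h2ao (6061 ± 152 TPM), a pair of histone H2A genes, came next after the 3 most abundant globins. The iron storage chains Fth1 and Ftl1 reached 4148 ± 325 and 3925 ± 325 TPM. The ribosomal protein genes among the 20 were Rplp1 (4396 ± 1039 TPM), Rpl41, Rpl28, Rpl18, Rps15, Rps26, Rpl27a and Rpl36. Oaz1, an inhibitor of ornithine decarboxylase, had 1705 ± 118 TPM, Josd2, a deubiquitinase, 1072 ± 172 TPM, and Ucp2, a mitochondrial carrier, 1013 ± 48.8 TPM. At a threshold of 1 TPM in both libraries 4514 genes were detected, of which 4296 are protein coding.

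Heme and iron genes were expressed at high but uneven levels. Of the 13 genes of heme synthesis and its transport steps, 12 had at least 1 TPM in both libraries. Alad, the second enzyme of the pathway, had 755 ± 0.686 TPM, the mitochondrial carrier Slc25a39 713 ± 176 TPM and Alas2, the erythroid rate-limiting enzyme, 237 ± 46.8 TPM. Of 13 genes of iron uptake and storage, 10 passed 1 TPM; after the ferritins came Glrx5, a factor of iron-sulfur cluster assembly, at 355 ± 5.35 TPM. Slc40a1, Aco1 and Ireb2 did not pass. The transferrin receptor Tfrc had 6.51 ± 0.544 TPM, and Ireb2, an iron-sensing regulator, 0.055 ± 0.00707 TPM. Both lists lay at percentile 100 of the random lists.

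All 23 genes of the red cell membrane and its skeleton passed 1 TPM in both libraries. Slc4a1, the anion exchanger band 3, led at 676 ± 122 TPM, ahead of Tmcc2 (468 ± 31.7 TPM) and the glucose transporter Slc2a1 (245 ± 11.4 TPM). Xk was lowest at 2.16 ± 0.212 TPM. The list lay at percentile 100 of the random lists.

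Transcription factors of the erythroid programme formed a graded series. Klf1, the erythroid Kruppel-like factor, had 386 ± 26.7 TPM, the Gata1 cofactor Zfpm1 376 ± 48 TPM and Lmo2 155 ± 13 TPM. Tal1 stood at 88.9 ± 17.7 TPM and Gata1 at 43.1 ± 8.17 TPM. Of the 20 factors 18 passed 1 TPM in both libraries, the exceptions being Hes6 and Bach1, a heme-regulated repressor and the lowest at 0.865 ± 0.00707 TPM. In erythropoietin signalling 6 of 11 genes passed 1 TPM, led by the survival factor Bcl2l1 (238 ± 13.9 TPM), the receptor Epor (92.5 ± 30.4 TPM) and the kinase Pim1 (57.4 ± 3.47 TPM), with Stat5a lowest at 0.215 ± 0.106 TPM. The factor list lay at percentile 100 and the signalling list at 99.6.

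Genes of late maturation and of cell division were both present. All 16 genes of organelle clearance and enucleation passed 1 TPM, with Ube2o, a ubiquitin-conjugating enzyme, at 81.2 ± 1.02 TPM, Trim10 at 44.3 ± 14.9 and the histone methyltransferase Kmt5a at 37.8 ± 4.09; Optn was lowest at 2.19 ± 0.488. Of 24 cell division genes 22 passed 1 TPM, with the cyclin Ccnd3 at 269 ± 0.368 TPM, the ribonucleotide reductase subunit Rrm2 at 86.5 ± 1.2 and Ccna2 at 45.8 ± 11.1, whereas Ccnb1 and Ccnd2 did not pass and Ccnd2 had 0.125 ± 0.00707 TPM. Among 7 cell cycle inhibitors 4 passed, namely Cdkn2d (32.1 ± 7.8 TPM), Cdkn2c (18.6 ± 0.0636), Cdkn1a (7.51 ± 0.792) and Cdkn1b (7.27 ± 0.382), and Cdkn2b had 0 counts in both libraries. Of these lists, clearance and cell division lay at percentile 100 and the inhibitors at 99.9.

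Redox, glycolytic and stress genes were also high. Of the redox genes 12 were measured and all 12 passed 1 TPM, led by Blvrb (916 ± 102 TPM), which reduces biliverdin, and the glutathione peroxidases Gpx4 (819 ± 175) and Gpx1 (629 ± 5.85), with the thioredoxin Txn1 lowest at 2.69 ± 0.735. In glycolysis 13 of 15 genes passed, with Gapdh at 631 ± 144 TPM, the red cell pyruvate kinase Pklr at 58.6 ± 0.651 and the hexokinase Hk1 at 52.4 ± 2.74, and with Pgk1 and Ldhb as the exceptions, Ldhb lowest at 0.115 ± 0.148. In the list of handling and stress genes 15 of 17 passed, with Jund at 539 ± 108 TPM, the heat shock genes Hspa1b at 493 ± 16.8 and Hspa1a at 190.0 ± 12.8, and Egr1 and Atf3 did not, Atf3 being lowest at 0.235 ± 0.106; Hspa1a and Hspa1b are near-identical copies. All 3 lists lay at percentile 100.

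The fixed list of cytoplasmic ribosomal protein genes, which leaves out Rplp0, Rplp1, Rplp2, Rpsa and Fau, took 1.91% ± 0.280 of TPM, and 2.59% ± 0.456 with these 5. In the list 75 of 79 genes passed 1 TPM, with Rpl41 highest at 2182 ± 588 TPM and Rpl10l at 0 counts. The replication-dependent histones took 1.68% ± 0.0806 of TPM, with 53 of 64 above 1 TPM, and after the leading pair Hist1h2ah had 86 ± 40.1 TPM; Hist2h3c2 had 0 counts. Messenger RNAs of the mitochondrial genome took 0.0907% ± 0.000518 of TPM, led by mt-Atp8 (187 ± 35.2 TPM), mt-Nd4l (143 ± 7.7) and mt-Atp6 (116 ± 54.7). The subunit mt-Co3 was listed at 0 TPM in both libraries, while Gm28437, a pseudogene copy of mitochondrial sequence on chromosome 1 (24613189 to 24613971), was assigned 5653 and 4727 counts. Other copies there were assigned 136 and 36.6 TPM (Gm28661), 7.89 and 93.3 TPM (Gm10925) and 113 and 99 TPM (Gm29216). The mitochondrial share leaves these copies out, so it may be too low and its small SD does not cover this. Levels of mitochondrial genes with such copies, and the order of the leading ones, are uncertain. These 3 lists each lay at percentile 100.

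Markers of progenitors and of other lineages were low, with no list of them outside the central 95% of random lists. That range began at 0 for each of these lists, so no median could lie below it. Kit, the receptor of early erythroid progenitors, had 36 and 9 counts, or 0.07 and 0.02 TPM. Gata2 had 0.815 ± 0.0495 TPM and Spi1, a myeloid factor, 0.86 ± 0.127 TPM, so that Klf1 exceeded Spi1 by 452 ± 35.9 times and Gata1 exceeded Gata2 by 53.3 ± 13.3 times. Of 15 early erythroid and progenitor markers 3 passed 1 TPM, which were Myc (4.56 ± 0.198 TPM), Runx1 (3.77 ± 0.163) and Itga4 (1.64 ± 0.233), and Mecom had 5 and 0 counts. The pan-leukocyte gene Ptprc had 0.035 ± 0.0212 TPM. The list medians lay at percentile 81.4 for progenitors, 92.0 for hepatoblasts and hepatocytes, 86.2 for macrophages, 93.5 for neutrophils, 78.8 for megakaryocytes and 79.5 for mast cells and basophils.

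Hepatocyte, macrophage, granulocyte and megakaryocyte markers were measured at low levels. Albumin (Alb), the main product of hepatocytes, had 0.675 ± 0.12 TPM, and the hepatic markers with the highest levels were Apoa1 (7.03 ± 1.44 TPM), Dlk1 (5.47 ± 0.226) and Trf (1.36 ± 0.898). Among macrophage markers the complement chains C1qc and C1qa had 5.54 ± 2.09 and 4.0 ± 0.75 TPM and Hmox1, a heme-degrading enzyme, 5.34 ± 1.91 TPM. Neutrophil markers were led by Mpo (4.28 ± 1.16 TPM), Prtn3 (3.69 ± 0.255) and Elane (1.93 ± 0.0566). Megakaryocyte markers were led by Gp9 (9.31 ± 1.41 TPM), Itga2b (2.25 ± 0.665) and Vwf (0.565 ± 0.29), and mast cell markers by Hdc (0.59 ± 0.339 TPM), Prss34 (0.565 ± 0.389) and Mcpt8 (0.45 ± 0.099). Clec1b, Ly6g, Serpina1b and Fcer1a had 0 counts in both libraries, which allows up to 3 counts, or 0.0586 CPM in library 1. Fcgr1 had 0 and 1 counts.

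Lymphoid, endothelial and stromal markers were also low. The T and NK, endothelial and stromal markers summed to 3.69 ± 0.502, 3.85 ± 0.318 and 1.65 ± 0.502 TPM. The 11 B lymphoid markers summed to 0.405 ± 0.0636 TPM, with Cd79a at 0.105 ± 0.0212, Pax5 at 0.10 ± 0.0424 and Cd79b at 0.060 ± 0.0424 TPM and Rag1 at 0 counts. Of the T and NK cell markers Lck had 3.62 ± 0.445 TPM, Trac 0.045 ± 0.0636 and Cd247 0.030 ± 0, and Gzmb had 0 counts. Endothelial markers were led by Egfl7 (2.5 ± 0.0354 TPM), Eng (0.685 ± 0.12) and Plvap (0.265 ± 0.106), with 1 and 0 counts for Tek. Stromal markers were led by Reln (1.36 ± 0.431 TPM), Des (0.090 ± 0.0707) and Cxcl12 (0.075 ± 0.0919), with 0 and 1 counts for Pdgfra. Xist, the X inactivation transcript of female cells, had 0.97 ± 0.396 TPM, and the Y-linked genes Eif2s3y, Ddx3y and Uty had 0.39 ± 0.17, 0.10 ± 0 and 0.015 ± 0.00707 TPM. These lists lay at percentiles 58.0 (B lymphoid), 6.49 (T and NK), 65.6 (endothelial), 34.6 (stromal) and 63.4 (sex-linked transcripts).

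**Figure D2:**
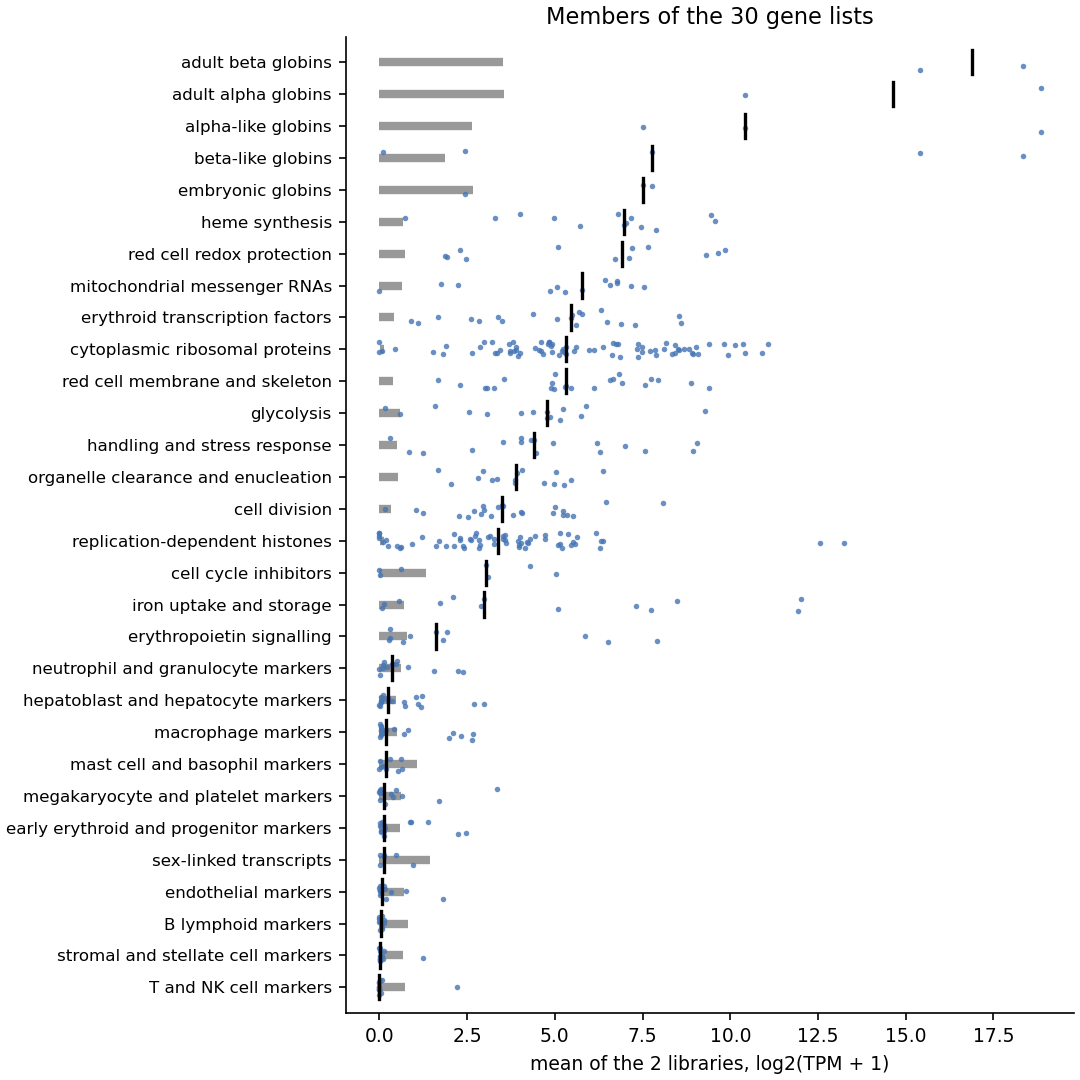
Members of each of the 30 gene lists (points), as the mean log2(TPM + 1) over the 2 libraries, with the list median as a black line. Grey bars are the central 95% of the medians of 10000 random lists of the same size drawn from protein-coding genes. The 19 lists with medians above their bars hold the globin, erythroid, metabolic, division, stress, mitochondrial, ribosomal and histone genes. The 11 lists with medians within their bars hold progenitor and other lineage markers and sex-linked transcripts.

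In all, 19 of the 30 lists lay above the central 95% of random lists, 0 below and 11 within. For each of those 11 the central 95% began at 0, the lowest level possible, so no median could lie below it. When random lists were drawn only from protein-coding genes with at least 1 TPM, 16 lists lay above and 11 below. On that background the medians of the cell cycle inhibitors (percentile 76.2), erythropoietin signalling (4.76) and the iron genes (81.3) were no longer outside the central 95%.

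Measured levels were higher in genes of higher GC content, taken as the mean over a gene's transcripts. Across 21449 protein-coding genes the Spearman correlation of GC content with log2(TPM + 1) was 0.285, and genes are not independent replicates, so no p is given. Among genes under 40% GC, 3.71% were detected in both libraries, against 9.15% at 40 to 45%, 15.9% at 45 to 50%, 25.4% at 50 to 55%, 33.2% at 55 to 60% and 29.0% at 60% or more. Tfrc (42.7% GC), Ireb2 (39.0%), Ptprc (41.2%), Xist (41.9%) and Eif2s3y (37.5%) lie on the GC-poor side of this range. Against random lists matched on GC content the count was again 19 of 30 lists above and 0 below.

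**Figure D3:**
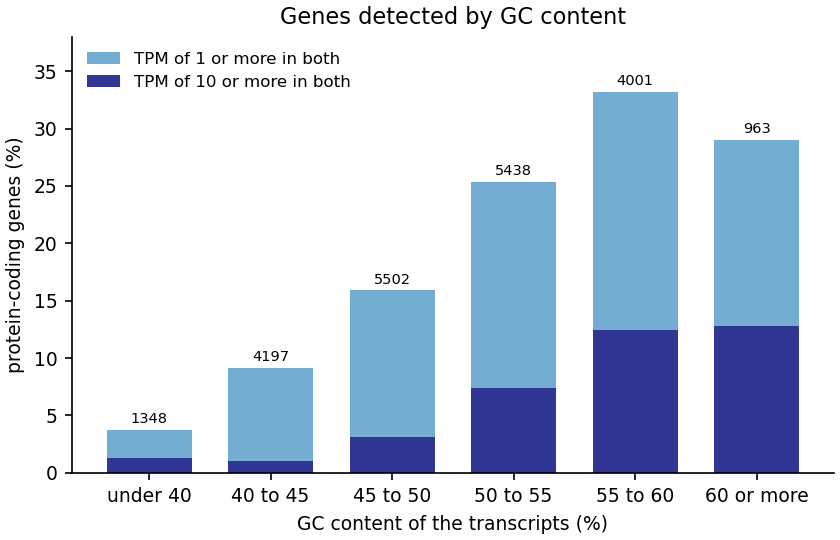
Share of protein-coding genes detected at 1 TPM or more in both libraries, in bins of transcript GC content. The share runs from 3.71% under 40% GC to 33.2% at 55 to 60%.

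Transcript shares were examined for 12 genes, of which Kit had too few counts. Of the transcripts of Gata1, Gata1-201 took 100% in both libraries. Klf1 and Add2 had a single annotated transcript each, so their share of 100% was fixed by the annotation. Slc4a1-201 held 98.8% ± 1.54 of Slc4a1 and Bcl2l1-201 held 93.3% ± 2.74 of Bcl2l1. In Ank1 the 8201-base transcript Ank1-207 took 52.8% ± 6.34, followed by the short Ank1-201, of 1030 bases, at 24.9% ± 5.76; by expected counts Ank1-207 held 86.3% and Ank1-201 held 3.51% and 5.67% in the single libraries. In Epb41 the transcript Epb41-218 took 56.3% ± 0.0778.

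Several of the leading shares were of short or non-coding transcripts. For Pklr the 345-base processed transcript Pklr-205 took 63.1% ± 21.3 of TPM but 15.2% of the expected counts, where the coding Pklr-202 held 71.1% and 86.8%. Alas2-204, a processed transcript of 569 bases, took 67.3% ± 11 of TPM and 34.2% of counts. A retained-intron transcript of 3527 bases, Tfrc-204, took 68.3% ± 17.0 of Tfrc. The same transcript led in both libraries for 11 of 11 genes by TPM share and for 10 by counts, and TPM share and counts named the same leader for 9. Klf1 and Add2, which had no other transcript, are in each of these counts. Among the globins, whose shares were looked at after the data were seen, the 494-base retained-intron transcript Hba-a1-202 took 55.0% of Hba-a1 TPM in library 1, whereas the coding Hba-a1-201, of 699 bases, took 96.2% in library 2. Hbb-bs-202, a retained-intron transcript of 549 bases, took 98.8% ± 0.304 of Hbb-bs TPM. The length-corrected levels of Pklr, Alas2 and the adult globins are therefore uncertain.

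The libraries were similar over abundant genes but differed by more than counting error at many. Across 16026 genes with a TPM above 0 in either library, log2(TPM + 1) had a Pearson correlation of 0.984 and a Spearman correlation of 0.886. Among 5257 genes with 100 or more counts in both libraries the median absolute log2 ratio was 0.24, and 97.1% lay within 2-fold. The biological coefficient of variation was 0.240 over 9043 genes. Of 10955 genes tested, 4833 (44.1%) differed between the libraries in an exact binomial test on the counts, 2457 higher in library 2 and 2376 higher in library 1. The test compares these 2 libraries, not conditions. Of the 4833, 1356 differed by 2-fold or more, 743 higher in library 2 and 613 higher in library 1. The mean chi-square per gene was 129, against a mean of 1 that sampling noise alone would give, and the median was 4.27.

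**Figure D4:**
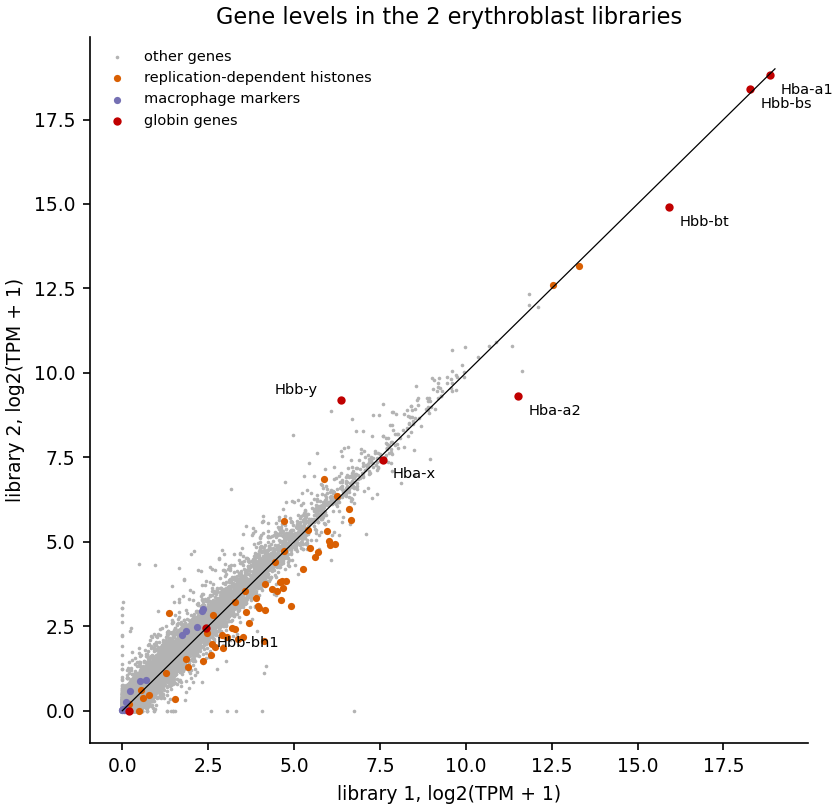
log2(TPM + 1) of each gene in library 2 against library 1, over 16026 genes with a TPM above 0 in either. Most of the abundant genes lie near the diagonal, and the Pearson correlation is 0.984.

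The largest differences in whole counts were in Hbb-y and a handful of less abundant genes. Hbb-y had 4155 counts in library 1 and 23342 in library 2, 6.45-fold higher after scaling (95% exact binomial interval 6.24 to 6.67). Padi4, a histone-modifying deiminase (chromosome 4, 140745865 to 140774236), had 0 counts in library 1 and 169 in library 2, at least 64.7-fold higher against a floor of 3 counts. Atox1, a copper chaperone, had 129 and 524 counts, 4.65-fold higher in library 2. Higher in library 1 were Epdr1 (148 and 18 counts, 6.99-fold), Emb (539 and 76 counts, 6.14-fold) and Lars2, the mitochondrial leucyl-tRNA synthetase (2104 and 390 counts, 4.70-fold). These 6 were the genes among the 20 named by the largest ratios whose counts were whole in both libraries.

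The other 14 of the 20 had counts that were not whole in at least 1 library, and their ratios are uncertain. As assigned, Trim17, Gm16867, Hist1h2br, Hist1h3e, Hba-a2, Hist1h3b and mt-Nd3 were higher in library 1. Higher in library 2 were Gm20662, Gm26938, Gm10260, Rnaset2b, Rps29, Kxd1 and Gm44503. For mt-Nd3, assigned 143 and 28.5 counts, the direction depends on how reads were divided. Gm28438, a pseudogene copy of mitochondrial sequence on chromosome 1, was assigned 0.11 and 133 counts. Trim17 (chromosome 11, 58954685 to 58973098) was assigned 1703 counts in library 1 and 0 in library 2, at least 495-fold, and overlaps the histone gene Hist3h2a on the same strand. Gm20662 was assigned 0 and 475 counts, at least 182-fold, and overlaps Ip6k1. Gm26938 was assigned 0 and 128 counts, at least 49.1-fold, and overlaps Tmem184a. Of the 20 genes, 6 overlap another gene on the same strand.

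As a group the replication-dependent histones were lower in library 2. Their median log2 ratio of library 2 to library 1 was -0.85, with 5 of 56 genes (Hist1h2ah, Hist1h4i, Hist3h2ba, Hist3h2a and Hist1h2bq) higher in library 2, against -0.11 to 0.10 for the central 95% of random lists of equal expression. Hist1h3e had 5.77-fold and Hist1h3b 4.27-fold more in library 1. In the binomial test 48 of 59 histone genes differed over all genes tested and 49 when adjusted over the list alone, and of the 48, 45 were higher in library 1. The summed counts of all copies had a log2 ratio of -0.24, and their share of TPM was 1.74% in library 1 and 1.62% in library 2. Most of these messages lack a poly(A) tail, and 5 other RNAs without a tail had a median log2 ratio of -1.47, 2 of them copies with equal counts.

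Macrophage markers and ribosomal protein genes were higher in library 2. Of the macrophage markers 8 of 8 with enough counts were higher in library 2, with a median log2 ratio of 0.50 (percentile 99.9), and with no minimum CPM the median was 0.20 (percentile 99.6); C1qc had 4.07 and 7.02 TPM and Hmox1 3.99 and 6.69. Among all 14 tested, 7 differed over all genes tested and 7 when adjusted over the list alone, 6 of them higher in library 2 and Mertk, with 13 and 2 counts, lower. The ribosomal protein genes had a median of 0.15 (percentile 99.9, 47 of 76 higher), and 63 of 76 differed by either adjustment, 41 of them higher in library 2. The cell division genes had a median of -0.15 (percentile 0.720, 9 of 24 higher in library 2), and 20 of 24 differed by either adjustment. Some lists that had not shifted had as high a part called, such as heme synthesis (12 of 13) and the red cell membrane (20 of 23). Others had less, such as the erythroid transcription factors (14 of 20). How many members were called, here and for the histones, therefore does not show a shift. In TPM the median of the cell division genes was -0.01 (percentile 0.960), where the median of all genes was 0.08, and their summed TPM was 687 and 709.

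The other 18 of 22 lists with enough members lay within the central 95% of matched random lists. By chance 1.1 of 22 would fall outside if the members of a list varied independently, which real lists need not do. The log ratio of library 2 to library 1 was also higher at higher GC content, with a Spearman correlation of 0.232 over 5093 genes. After correction for that trend the cell division list was no longer outside the range, at percentile 9.81.

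**Figure D5:**
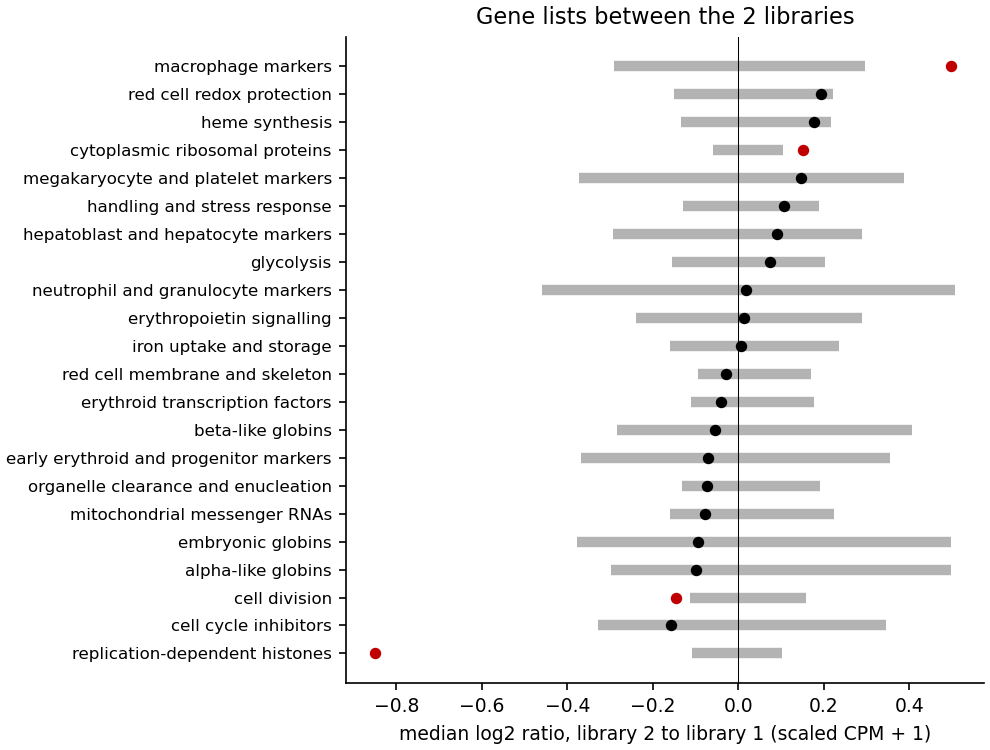
Median log2 ratio of library 2 to library 1 for each of 22 gene lists (points) beside the central 95% of 10000 random lists matched on expression (grey bars), with lists outside in red. Histones lie at -0.85 and macrophage markers at 0.50.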

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

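The GC-corrected ratios, the GC-matched lists and the globin share of 3 genes were tests chosen after the data were seen; the other alternatives were planned. Genes detected numbered 8398 at 0.1 TPM, 2071 at 5 TPM, 1311 at 10 TPM and 9090 at 10 or more counts, and 4724 and 4918 in the single libraries. Genes apart between the libraries numbered 1356 with an absolute log2 ratio of 1 or more and 3852 to 4833 under the other settings. Over genes with a mean of 1 TPM or more the Pearson correlation was 0.968 and the Spearman correlation 0.938; with posterior mean TPM the latter was 0.940. The coefficient of variation was 0.110 from the median gene-wise dispersion of DESeq2, a different estimator, and 0.320 without a filter on low counts. In expected counts, which are not corrected for length, the globin share was 72.3% and the ratio of alpha-like to beta-like globins 1.45. In TPM of single libraries these were 84.4 to 86.0% and 1.23 to 1.27, and the embryonic share of beta-like globins ran from 0.0228 to 0.155%, so that 1 library decides it. The count of 19 lists above random lists held under 6 other settings and was 16, with 11 below, against genes of 1 TPM or more. That background lies higher, and on it the T and NK, stromal, B lymphoid, progenitor, endothelial, hepatoblast, macrophage, mast cell, megakaryocyte, neutrophil and sex-linked lists all fell to percentile 0, of which only the first 2 had lain under 50 before. Erythropoietin signalling fell from 99.6 to 4.76, so that its side depends on the background. Lists apart between the libraries numbered 6 with no minimum, where glycolysis (percentile 98.4) and neutrophil markers (98.6) joined, and 3 after GC correction, where cell division (9.81) dropped out. At a mean CPM of 10 or more, heme synthesis joined at 98.8, and too few macrophage markers remained for a value. Within the central range lists also crossed the middle, as the shift of mitochondrial messages did from percentile 15.5 to 85.7 after GC correction; where no construction is named, the cause was not tested. Depth limits genes under 100 counts most.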

Other observations

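The tests of GC bias, of both explanations for Hbb-y, of S phase and of histone copies were chosen after the result was seen; those of transcript length, single-library depth and poly(A) selection were not, although 1 polyadenylated histone variant, H3f3a, had been seen. The genes in this part were chosen after their values were seen. Mt2, a metal-binding metallothionein, had 631 ± 10.3 TPM (SD, n = 2) and Mt1 178 and 427 TPM, while Mt3 and Mt4 had 0 counts. Of 325 genes of ubiquitin conjugation and ligation 97 passed 1 TPM in both libraries, with Ube2s at 240 ± 42.0, Ube2c, a mitotic enzyme, at 180 ± 2.05 and Rnf10 at 109 ± 0.205 TPM. Rnf123 had 111 and 307 TPM from 25297 and 25941 counts, 1 of 33 genes among 5257 whose TPM ratio lay 2-fold or more from their count ratio. Bsg, a membrane glycoprotein, had 900.0 ± 64.8 TPM.

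Of 371 solute carrier genes 57 were detected; beside those in the lists, the glycine transporter Slc6a9 had 96.5 ± 17.7 TPM, the nucleoside transporter Slc29a1 95.6 ± 4.79 and the heme transporter Slc48a1 31.9 ± 5.78. Of 17 Kruppel-like factors 8 were detected, with Klf3 at 50.2 ± 1.02 and Klf16 at 22.2 ± 2.72 TPM after Klf1, whereas 0 of 39 Hox genes passed 1 TPM. Among histone variants H3f3a had 733 ± 48.1, H2afx 431 ± 86.5 and H2afz 367 ± 105 TPM. In autophagy Gabarap, a conjugated autophagosome protein, reached 62.8 ± 14.5 TPM. Of non-coding transcripts Gm42418 had 3207 and 1074 TPM and Lockd, a transcript beside a cell cycle inhibitor gene, 38.8 ± 1.34 TPM.

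Members of stable complexes differed in level along with their GC content. Within 12 complexes of 139 genes the median Spearman correlation of GC content with level was 0.776, positive in 11 of 12, against -0.22 to 0.23 when GC values were shuffled within complexes. Transcript length did not account for it, since the median was 0.730 after a partial correction for length. The correlation did not rest on 1 library, since the lower of the 2 libraries gave 0.755. Both libraries had similar depth, so an effect of depth common to them could not be tested. GC bias in the libraries remains a candidate explanation, and would lower the measured level of GC-poor genes. No biological explanation was tested.

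Hbb-y was 6.45-fold higher in library 2. If more cells making all 3 embryonic globins were the source, Hba-x and Hbb-bh1 would rise by a large part of its log2 ratio of 2.69, yet the larger of the upper ends of their 95% exact intervals was 0.187. This does not cover cells that make Hbb-y with little Hba-x and Hbb-bh1, so more cells of that kind are not excluded. Reads shared with other globin genes are argued against by its sequence, since 0% of its 31-base words occur in transcripts of another gene, against 54.4% for Hbb-bs, and its counts were whole in both libraries. A difference between the pools of embryos may remain, as may a difference in strain, although the labels give both libraries the same donor entry. Neither was tested.

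The lower level of replication-dependent histones in library 2 was set against 3 explanations. Fewer cells in S phase would be expected to lower other S phase genes too. The median log2 ratio of 22 such genes was 0.0651 (SD over genes 0.382), with 13 higher in library 2 and Slbp lowest at -0.50. How closely these genes follow the share of cells in S phase is not known from these data, so a smaller change is not excluded. Reads shared between histone copies remain open, since only 4 of the 56 copies had at most 5% of their 31-base words in another gene; their median was -0.793 (SD over genes 0.375) with 0 higher in library 2, and the summed counts of the family had -0.24, or -0.68 without the 2 most abundant copies. Other RNAs without a tail, namely Rn7sk, Rmrp, Rpph1 and the copies Rn7s1 and Rn7s2 with equal counts, had a median of -1.47, or -1.20 with the copies taken as 1, and 0 of 5 were higher in library 2, while 8 polyadenylated histone variants had 0.20 with 5 higher. Less complete poly(A) selection in library 1 remains a possible explanation, and no biological one beyond S phase was tested.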
